A study of Mus musculus with 48 samples.

How the data were processed

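Gene expression was measured in 48 cultures of mouse 32D cells, a myeloid progenitor line, made to express the p210 BCR/ABL oncoprotein. Each culture was hybridised to 1 Affymetrix MOE430_2 array, per the labels. The cells carried the MigRI retroviral vector, either empty or with C/EBPα fused to the hormone-binding part of the estrogen receptor (C/EBPα-ER), which 4-hydroxytamoxifen (4-HT) activates. The 3 fusions were wild type (WT), K298E, which the labels call unable to bind DNA, and Δ(177-191), which the labels call unable to interact with CDK2 and CDK4. Each of the 4 lines was sampled at 0, 6, 9 and 12 h after 4-HT with 3 arrays, which makes 16 groups. The labels speak of triplicates in one place and of 3 separate experiments in another, and they do not tie the replicate numbers to the experiments. They describe 1 line per construct and no untreated culture at a later time.

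The deposited values are MAS5 signal intensities on a linear scale, in whole numbers, per the submitters' processing notes and the values themselves; the MAS5 version is not stated. The deposited arrays share 1 scale: without the lowest and highest 2% of probe sets the mean signal lay between 99.96 and 99.98 on every array. Detection calls were not used here. The table holds 45101 probe sets, of which 64 controls were left out. Of the other 45037, the platform annotation gives 1 gene symbol for 34945, several for 932 and none for 9160. Symbols were updated by gene identifier from a RefSeq gene table of assembly GRCm38.p6, which was used for names alone.

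Signals were transformed as log2(signal + 3), where 3 is the 20th percentile of all signals. A probe set was tested if at least 1 of the 16 group means exceeded the median of all log2 values, 4.09, which is a signal of 14. This left 27167 probe sets, 22970 of them with 1 symbol, 642 with several and 3555 with none. For counts of genes and for gene lists, each of the 12800 genes was represented by the probe set with the highest mean over the 48 arrays. Because of the added 3, changes of genes with low signals are understated, and folds of genes near a signal of 0 depend on it.

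Linear models with 16 group means were fitted in limma 3.58.1 (R 4.3.3, statmod 1.5.0), with moderated tests that let the variance follow the mean and 32 residual degrees of freedom. A result passed the threshold at a two-sided adjusted p under 0.05 by the method of Benjamini and Hochberg over the probe sets tested. For each construct at each time, the change from 0 h minus the change in vector cells was tested, which is called the relative change. The mean change over 6, 9 and 12 h was compared between WT and each mutant and between each construct and vector. Vector cells after 4-HT were compared with vector cells at 0 h, and each construct line with the vector line at 0 h. Errors of log2 changes are standard errors of the model, and errors of signals are standard deviations (SD) of 3 arrays. All p-values measure only the spread between these arrays, which come from 1 line per construct.

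The 25 gene lists were primary granule, secondary and tertiary granule, phagocyte oxidase and granulocyte receptors, monocyte and macrophage, stem and progenitor transcription factors, progenitor surface receptors, mast cell, basophil and eosinophil, erythroid and megakaryocyte, lymphoid, fibroblast and stromal, G1/S and DNA replication, G2/M and mitosis, CDKs, cyclins D and CDK inhibitors, Myc and ribosome biogenesis, BCR/ABL and STAT5 targets, apoptosis and survival, sterol biosynthesis, estrogen receptor targets, amino acid and stress response, interferon response, immediate early, C/EBP family and partners, ID and basic helix-loop-helix, hypoxia and glycolysis, and cytosolic ribosomal proteins. They had 649 entries, of which 502 were tested, and 1 member was renamed through a synonym. Some genes stand in more than 1 list. Each list was tested against the other genes with camera at a preset correlation of 0.01, adjusted over the 25 lists of a comparison. An estimated correlation, fry, all probe sets of each member and a replicate block were alternatives. The lists, the model, the comparisons after 4-HT and at 0 h, and the rule for named genes were fixed before the data were examined. List tests of the lines at 0 h, the division of the calls into construct and vector changes, the recount of that division with vector arrays left out and under other scalings, and list tests under other scalings were added afterwards.

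Genes were named by rule: at 12 h, for each construct against vector, the 10 highest and 10 lowest relative changes past the threshold; for WT minus each mutant, for vector cells after 4-HT and for each line at 0 h, the 5 highest and 5 lowest; for each list in each main comparison, up to 2 rises and 2 falls; and always Myb, Gata2, Cebpa, Esr1, Cebpe, Csf3r, Gfi1, Cebpb, Cebpd, Cebpg, Spi1, Gata1, Kit, Mpo, Id1, Id2, Id3, Myc, Cdk2, Cdk4, Cdkn1a, Abl1 and Bcr. Cebpe was not analysed here, and Id3 did not pass the filter on low signals.

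Overlaps of calls between constructs share the vector arrays. They are given beside the overlap of independent lists of the same sizes, and correlations beside the mean of 100 simulations. In these, all groups, the shared control included, were drawn as noise without any change. Whether other splits of the arrays call as many probe sets was counted over 100 drawn splits, or over all 10 where 3 arrays face 3.

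Arrays carry no count depth, so the number of arrays limits the precision. Over the 10746 probe sets with a mean signal of 100 or more, the correlation between arrays of a group ran from 0.970 to 0.993 and the median SD of log2 values within a group was 0.106. The method was tested on simulated data for WT relative to vector at 12 h, with 50 changed probe sets per size among 27167. It recovered 16% at a log2 change of 0.5, 50% at 1, 62% at 2 and 92% at 3, and 9 of the 119 calls were of unchanged probe sets. The share at 2 was below the mark first set for this test, which was then dropped. A simulated shift of 0.5 in 1 list of the 25, over 12800 genes, was called, with 0 calls among the others. The simulated noise was independent between genes, so this run does not test list calls among correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

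The alternatives tried were pseudocounts of 1 and 12, no filter, a filter on the mean over all arrays, quantile normalization, median centring, a replicate block, array weights, the arrays of the compared groups alone, the change from a line's own 0 h, the construct against vector at the same time, and leaving out each array and each replicate number. Added after the data were examined were a pseudocount of 32, a minimum signal of 50 in 1 group, and leaving out the 4 arrays with the highest 99.8th percentile of signal.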

Results

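The 48 arrays covered 4 lines of BCR/ABL-expressing mouse 32D cells at 4 times after 4-HT, with 3 arrays in each of the 16 groups. The median signal of an array lay between 11 and 19. The share of probe sets at 0 lay between 0.324% and 3.40%. The ratio of the 3' to the 5' Gapdh control probe sets ran from 0.715 to 0.880, and that of the actin controls from 1.06 to 1.48. No pair of arrays held identical values. The first principal component held 55.0% of the variance of the probe sets with signals of 100 or more and the other main one 12.9%. On the first, the Δ(177-191) arrays lay apart at 33.6 to 62.6, already at 33.6 to 34.3 at 0 h. The arrays of the other lines lay at -28.7 to -5.00.

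The Esr1 probe set with the highest mean signal, for the estrogen receptor gene of which the fusion carries a part, served as a check of the labels. Its signal at 0 h was 18.3 ± 1.15 (SD, n = 3) in vector cells, 2475 ± 214 in WT, 1439 ± 145 in K298E and 3263 ± 446 in Δ(177-191) cells. At 12 h it was 18.7, 2173, 1006 and 3349. On this probe set all fusion lines were far above vector cells, and K298E cells were below WT cells. The 2 other Esr1 probe sets did not set the lines apart in this way: on the brighter one the signal at 0 h was 102.7 in vector, 95.3 in WT, 78.7 in K298E and 212 in Δ(177-191) cells.

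**Figure D1:**
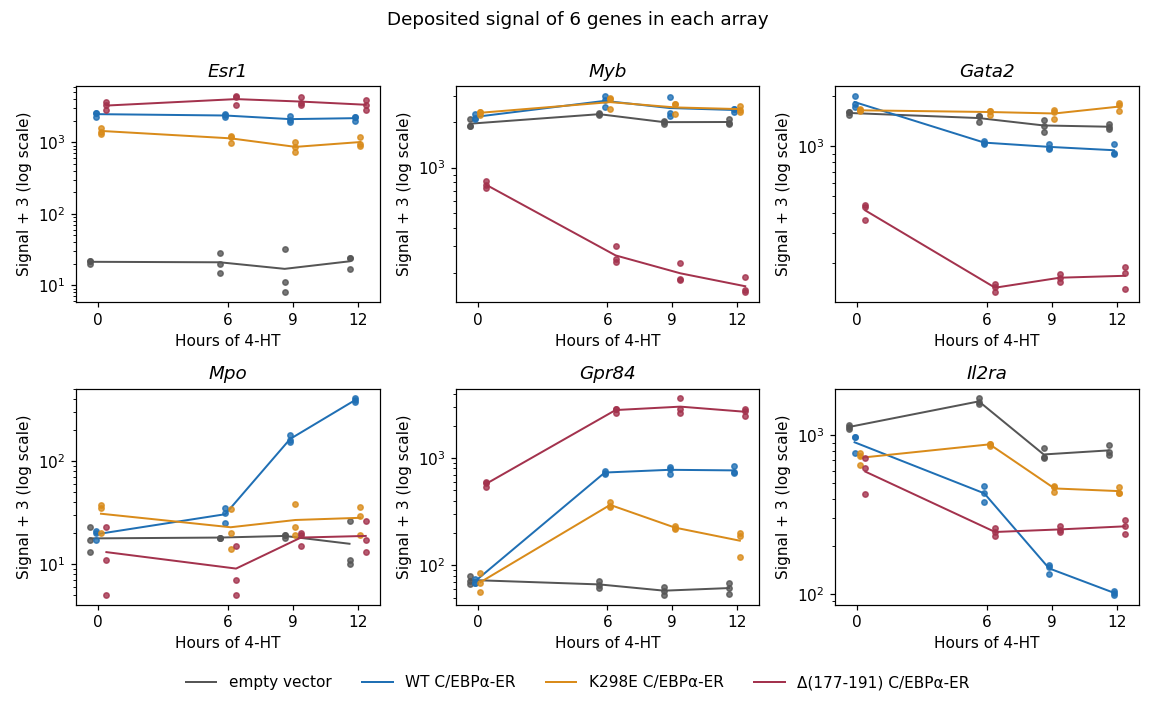
Signal intensity of 6 genes on each array (points; log scale) against hours after 4-HT, for vector, WT, K298E and Δ(177-191) cells, with lines through the means of 3 arrays. Mpo was higher in WT cells at 12 h (385) than in vector cells (12.7), and Myb was lower in Δ(177-191) cells at 12 h (160.3) than at 0 h (768).

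The title of the series names c-Myb and GATA-2, transcription factors of blood progenitors, as genes repressed by C/EBPα. Gata2 fell in WT cells, from a signal of 1841 ± 149 (SD, n = 3) at 0 h to 945 ± 76.1 at 12 h, while vector cells went from 1583 ± 31.6 to 1309 ± 40.5. Its relative log2 change in WT was -0.69 ± 0.12 (adjusted p = 6.78e-05), and 9 of 9 treated arrays lay below every 0 h array in both lines. In K298E cells it was 0.35 ± 0.12 (adjusted p = 0.0941), and in Δ(177-191) cells, where the signal was already at 409 at 0 h, Gata2 fell to 164 at 12 h, a relative change of -1.03 ± 0.12 (adjusted p = 5.45e-09). The mean change differed between WT and K298E by -0.88 ± 0.10 (adjusted p = 4.42e-09).

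Myb did not pass the threshold in WT cells. Its signal was 2166 ± 76.8 at 0 h and 2409 ± 58.1 at 12 h, against 1953 ± 118 and 2005 ± 86.4 in vector cells (n = 3 each), a relative log2 change of 0.11 ± 0.14 (adjusted p = 0.82). Of the 9 treated WT arrays 8 lay above every WT array at 0 h and 0 below. In K298E cells the relative change was 0.04 ± 0.14 (adjusted p = 0.956). In Δ(177-191) cells Myb fell from 768 ± 36.4 to 160.3 ± 20.6, a relative change of -2.28 ± 0.14 (adjusted p = 2.35e-16), with 9 of 9 treated arrays below every 0 h array. The difference between WT and Δ(177-191) in the mean change was 2.15 ± 0.12 (adjusted p = 5.99e-18). The other 2 probe sets of Myb gave 0.61 ± 0.28 and 0.96 ± 0.43 in WT (adjusted p = 0.257 and 0.262) and -1.53 ± 0.28 and -1.83 ± 0.43 in Δ(177-191) (adjusted p = 3.81e-05 and 0.00151). Without replicate 2 the adjusted p of Gata2 in WT was 0.0561, against 3.84e-05 to 0.0561 over all 15 left-out settings. With quantile normalization the Gata2 change in K298E passed the threshold as a rise (0.41).

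The WT line was compared with vector to ask which transcripts respond when C/EBPα, a transcription factor needed for granulocyte differentiation, is activated. Genes of granulocytes and phagocytes were among the 10 largest rises at 12 h. The signal of Mpo, the myeloperoxidase of primary granules, was 16.3 ± 2.08 at 0 h and 385 ± 17.7 at 12 h in WT cells and 12.7 ± 8.96 in vector cells at 12 h (SD, n = 3), a relative log2 change of 4.61 ± 0.57 (adjusted p = 7.89e-08). All 9 of 9 treated WT arrays lay above every 0 h array. Gpr84, a fatty acid receptor of phagocytes, rose by 3.69 ± 0.18, Lcn2, a siderophore-binding granule protein, by 3.18 ± 0.20, Anxa3, an annexin of neutrophils, by 3.12 ± 0.27 and the chemokine receptor gene Ccr1 by 2.83 ± 0.28. The cytokine gene Il4 rose by 3.62 ± 0.37, Tnfrsf14, a receptor of the TNF receptor family, by 3.57 ± 0.58 and Vsir, an immune checkpoint gene, by 3.03 ± 0.23. Igsf6 (5.33 ± 0.50) and Hp, the gene of haptoglobin (3.25 ± 0.40), were at signals of 1 to 1.33 in vector cells at 12 h, so their folds depend on the added 3.

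Among the 10 largest falls were Il2ra, the α chain of the interleukin 2 receptor, and Podxl, a sialomucin. Il2ra went from 901 ± 113 to 99 ± 3 in WT cells and from 1126 ± 30.8 to 801 ± 59.7 in vector cells (SD, n = 3), a relative log2 change of -2.65 ± 0.16 (adjusted p = 4.21e-16). All 9 of 9 treated WT arrays lay below every 0 h array. Podxl fell by -2.91 ± 0.24 on the same scale, Pglyrp2, a peptidoglycan-binding protein gene, changed by -2.68 ± 0.19, C1qtnf1 by -3.05 ± 0.41 and Fam20a by -2.48 ± 0.46. The other 5, Jam3, Tshr, Taar1, Svs5 and Mir205hg, had no group mean above 29 in any line, so these falls lie near the floor of the signal. Those of Jam3 (with no filter) and Mir205hg (with a pseudocount of 12) no longer passed.

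Of the granule lists in WT cells, the one named primary granule had 4 members higher and 1 lower of 9 tested (adjusted over the list alone, 5 higher and 2 lower). Among these members were Mpo and Hp and, lower, the protease inhibitor gene Serpinb1a (-1.27 ± 0.17). Membership of the list does not by itself place a product in these granules. The list was higher against other genes (adjusted p = 0.000979). Of the secondary and tertiary granule genes 3 of 15 were higher and 0 lower (adjusted over the list alone, 4 higher and 1 lower; adjusted p = 0.00331). Phagocyte oxidase and granulocyte receptors had 8 of 21 higher and 0 lower (adjusted over the list alone, 11 higher and 0 lower; adjusted p = 5.32e-08). Among them were Itgam, the integrin CD11b (2.78 ± 0.23), and the Fc receptor gene Fcgr2b (2.7 ± 0.19). The mast cell, basophil and eosinophil list had 4 of 12 higher and 1 lower (adjusted over the list alone, 4 higher and 1 lower; adjusted p = 0.00812). Its rises included the cytokine genes Il4 and Il6 (1.65 ± 0.39), which other cells express too, and its fall was Slc18a2, a monoamine transporter gene (-0.91 ± 0.12).

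Of the stem and progenitor transcription factors 8 of 24 were lower and 3 higher (adjusted over the list alone, 4 higher and 8 lower; adjusted p = 0.00722). Zfpm1, the GATA cofactor FOG-1, fell (-1.86 ± 0.15), as did the corepressor gene Cbfa2t3 (-0.92 ± 0.13), while Lmo2 (0.65 ± 0.13) and Runx1 (0.79 ± 0.23) were higher. The ID and basic helix-loop-helix list had 3 of 11 lower and 1 higher (adjusted over the list alone, 1 higher and 4 lower; adjusted p = 0.00541). Tal1 was at -0.88 ± 0.10 and Id2 at 0.64 ± 0.17. BCR/ABL and STAT5 targets had 7 of 26 lower and 1 higher (adjusted over the list alone, 1 higher and 9 lower; adjusted p = 0.000475). Il2ra and the phosphatase gene Dusp4 (-1.22 ± 0.12) fell and Gfi1, a repressor needed for granulocytes, rose (1.58 ± 0.14).

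Sterol biosynthesis had 5 of 20 lower and 0 higher (adjusted over the list alone, 0 higher and 10 lower; adjusted p = 0.000148). The isomerase gene Idi1 was at -0.85 ± 0.12 and Msmo1 at -1.13 ± 0.32. Amino acid and stress response had 8 of 25 lower and 1 higher (adjusted over the list alone, 1 higher and 11 lower; adjusted p = 5.38e-05). The pseudokinase gene Trib3 was at -1.32 ± 0.21 and Nupr1, a stress response gene, at 1.31 ± 0.16. For 5 further lists the call was lost with an estimated correlation. Myc and ribosome biogenesis (3 higher and 1 lower of 37; adjusted p = 0.0117) had an adjusted p = 0.107 with an estimated correlation, and hypoxia and glycolysis (3 higher and 0 lower of 24; adjusted p = 0.0455) one of 0.313 with an estimated correlation. Apoptosis and survival (0 higher and 3 lower of 18; adjusted p = 0.0295) had 0.0605, and estrogen receptor targets (0 higher and 2 lower of 13; adjusted p = 0.0295) had an adjusted p = 0.132 with an estimated correlation. The cytosolic ribosomal proteins (0 of 29 past the threshold; adjusted p = 0.0196, downward) had an adjusted p = 0.658 with an estimated correlation, and their direction turned with quantile normalization. Adjusted over the list alone, these 5 lists had 3 higher and 1 lower, 4 higher and 1 lower, 0 higher and 4 lower, 0 higher and 2 lower and 0 higher and 0 lower, in the order named.

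The other 11 lists did not pass in WT cells. They were monocyte and macrophage (2 higher and 1 lower of 20), progenitor surface receptors (1 and 4 of 10), erythroid and megakaryocyte (0 and 1 of 13), lymphoid (0 and 0 of 8), fibroblast and stromal (1 and 0 of 10), G1/S and DNA replication (0 and 1 of 39), G2/M and mitosis (0 and 0 of 34), CDKs, cyclins D and CDK inhibitors (2 and 2 of 23), interferon response (1 and 2 of 23), immediate early (2 and 0 of 21) and C/EBP family and partners (4 and 1 of 17). The smallest adjusted p among them was 0.0718, of interferon response. The median and the mean of the monocyte list differed in sign (-0.03 and 0.12), as did those of the C/EBP family (-0.08 and 0.10) and of the immediate early list (-0.01 and 0.06). The CDK list had a mean of 0.07 and a downward test. Among single genes, Gadd45a, an inhibitor of cell cycle progression, rose (2.27 ± 0.23), and Spi1, the gene of PU.1, rose (0.67 ± 0.14). Myc was higher relative to vector (0.76 ± 0.13), without passing as a rise from the line's own 0 h. Cdk2, Cdk4, Cdkn1a, Csf3r, Cebpa, Cebpb, Cebpd, Cebpg, Id1, Gata1, Kit, Abl1 and Bcr did not pass the threshold in WT cells, with Cebpa at -0.62 ± 0.20 (adjusted p = 0.0704). A further Cebpb probe set did pass in WT cells (0.42 ± 0.12, adjusted p = 0.0246).

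In all, 1461 of 27167 probe sets passed the threshold in WT relative to vector at 12 h, 773 higher and 688 lower, and 245 and 195 of them by 2-fold or more. In genes, 488 were higher and 431 lower of 12800. At 6 h 1295 probe sets passed, 688 higher and 607 lower (748 and 422 with median centring), and at 9 h 1255, 682 higher and 573 lower. Of the genes called at 12 h, 261 of the 488 and 207 of the 431 passed in the same direction at all 3 times. Of the 488 higher genes, 390 also passed as a rise from the WT line's own 0 h, and in 87 the vector fall alone passed. Of the 431 lower genes, 417 passed as a fall from the line's own 0 h. Leaving out replicate 2 of every group lowered the count at 12 h to 689, and array weights raised it to 2221.

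The K298E line was compared with vector to ask what the fusion does without binding DNA. Most of its relative changes went with a change in the vector line. The gene of galectin 3, Lgals3, a lectin of macrophages, was at 73.3 ± 5.03 and 105 ± 18.5 in K298E cells at 0 and 12 h. It fell from 77.7 ± 12.7 to 13.7 ± 4.62 in vector cells (SD, n = 3). The relative log2 change was 2.78 ± 0.23 (adjusted p = 3.36e-11). Of the 431 genes higher in K298E relative to vector at 12 h, 69 passed as a rise from the line's own 0 h, and for 340 the vector fall alone passed. Of the 286 lower genes 13 passed as a fall from the line's own 0 h, and for 258 the vector rise alone passed. The change from its own 0 h passed for 2507 probe sets in K298E cells at 6 h, 1035 at 9 h and 488 at 12 h. In vector cells it passed for 4222, 4056 and 3699, in WT for 7099, 6754 and 6914, and in Δ(177-191) for 6693, 7285 and 6856. The division of calls into line and vector changes was made at 12 h alone.

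Some genes rose in K298E cells themselves. Adam8, a metalloprotease gene of leukocytes, went from 317 ± 16.2 to 716 ± 188 (relative log2 change 2.64 ± 0.14). Il18r1, a receptor chain for interleukin 18, went from 54 to 112 (2.48 ± 0.24). Prtn3, the proteinase 3 of primary granules, went from 689 ± 37.8 to 1691 ± 501 (1.83 ± 0.19). The placental growth factor gene Pgf (2.5 ± 0.51) and Col9a3 (2.26 ± 0.66) were also among the 10 highest relative to vector, but did not rise past the threshold from the K298E line's own 0 h. In vector cells both fell, with 9 of 9 treated arrays below every 0 h array. The remaining 5, which did not pass from the line's own 0 h either, Col11a2, Eif5a2, Coq8a, Cd14 and Hdc, had no group mean above 48.3 in vector or K298E cells, and Hdc was at 1.67 to 2.67 in K298E cells throughout. Among the 10 lowest relative to vector were Aven, an apoptosis inhibitor gene (-1.25 ± 0.20), Ssx2ip (-1.21 ± 0.29), the ribosome biogenesis genes Rrp12 (-1.01 ± 0.23) and Ddx21 (-0.91 ± 0.12). So were the chaperone gene Hsph1 (-0.84 ± 0.10), Shmt1, an enzyme of folate metabolism (-0.82 ± 0.18), and Casp1, the inflammatory caspase (-0.97 ± 0.25). Taar1, Olfr15 and Rnf112 completed them at group means of at most 18.7 in both lines. Of the 7 genes named before these, Casp1 alone passed as a fall from the K298E line's own 0 h. Taar1, Olfr15 and Col9a3 lost their call with no filter, Casp1 with a pseudocount of 12, and Cd14, Coq8a, Hdc and Casp1 with the compared arrays alone. The relative change of Casp1 was -0.31 with a pseudocount of 12 and -0.03 with 32, so this fall depends on the added 3.

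Of the lists in K298E relative to vector, 10 passed, and each also with an estimated correlation. G1/S and DNA replication had 9 of 39 lower (adjusted over the list alone, 0 higher and 19 lower; adjusted p = 1.38e-14). Lower relative to vector were the cyclin gene Ccne1 (-0.76 ± 0.17) and the replication licensing gene Cdc6 (-0.68 ± 0.17). Both rose in vector cells, with 9 of 9 treated arrays above every 0 h array. In K298E cells Cdc6 lay above on 9 and Ccne1 on 3, with 0 below. Myc and ribosome biogenesis had 13 of 37 lower and 2 higher (adjusted over the list alone, 2 higher and 21 lower; adjusted p = 1.38e-14). Hypoxia and glycolysis had 8 of 24 higher (adjusted over the list alone, 13 higher and 0 lower; adjusted p = 1.38e-11). Higher relative to vector were Ndrg1 (1.25 ± 0.15) and the oxygen sensor gene Egln3 (1.24 ± 0.13). Both fell in vector cells, with 9 of 9 treated arrays below every 0 h array. In K298E cells Ndrg1 lay below on 6 and above on 1, and Egln3 below on 3 and above on 6. Monocyte and macrophage had 8 of 20 higher (adjusted over the list alone, 9 higher and 0 lower; adjusted p = 5.95e-09). Phagocyte oxidase and granulocyte receptors had 5 of 21 (adjusted over the list alone, 7 higher and 0 lower; adjusted p = 3.26e-05) and secondary and tertiary granule 3 of 15 (adjusted over the list alone, 3 higher and 0 lower; adjusted p = 0.0106). Immediate early (3 of 21 higher; adjusted p = 0.00062), mast cell, basophil and eosinophil (2 of 12; adjusted p = 0.00278), C/EBP family and partners (3 of 17; adjusted p = 0.00553) and apoptosis and survival (3 of 18; adjusted p = 0.0214) were higher relative to vector as well, with 0 members lower in each. Adjusted over the list alone, these had 3 higher and 0 lower, 2 higher and 0 lower, 5 higher and 0 lower and 3 higher and 0 lower, in the order named. Cebpa was among the higher genes (1.28 ± 0.20): it fell in vector cells from 190.3 to 45.7 and in K298E cells from 418 to 254.

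In K298E relative to vector, 1142 probe sets passed at 12 h, 672 higher and 470 lower, 193 and 17 of them by 2-fold or more. The counts were 256 at 6 h, 221 higher and 35 lower, and 1057 at 9 h, 640 higher and 417 lower. Of the genes called at 12 h, 99 of 431 higher and 8 of 286 lower passed at all 3 times. The split of these calls depended on the scaling: with median centring 427 were higher and 749 lower at 12 h, and 438 and 569 at 9 h. Without replicate 2 of every group 313 probe sets passed at 12 h and 63 at 6 h, without K298E 6 h replicate 2 alone 170 passed at 6 h, and array weights gave 1972 at 12 h.

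The Δ(177-191) line tests the fusion without its CDK2 and CDK4 interaction. Chemokine genes were among the genes that rose in it. Ccl4, a chemokine of activated macrophages, went from 142 ± 20.2 to 1066 ± 96.9 (SD, n = 3) and was at 36 and 30.3 in vector cells. Its relative log2 change was 3.12 ± 0.28 (adjusted p = 1.03e-11). Ccl3 rose by 4.44 ± 0.70 and was among the 10 highest. The paired receptor gene Pilra (4.72 ± 0.45), the matrix glycoprotein gene Emilin1 (4.0 ± 0.18), Cst7, an inhibitor of cathepsins (3.9 ± 0.29), the chitinase-like gene Chil1 (3.63 ± 0.69) and Nupr1 (3.29 ± 0.16) were among them too. Cd3d (4.48 ± 0.73), Slc6a12, Lpxn and Gbp6 completed them at group means of at most 59.7. The transporter gene Spns2 fell from 884 ± 69 to 56.3 ± 7.64, a relative change of -3.9 ± 0.16 (adjusted p = 3.04e-22). Cep63, a centrosome gene (-2.8 ± 0.13), the kinase gene Camk2a (-3.66 ± 0.39) and the potassium channel gene Kcnn4 (-2.8 ± 0.19) fell. Falls also came in Cd244a (-3.24 ± 0.48), Gem (-3.58 ± 0.41), Gzmb (-3.26 ± 0.61), Krt80 (-2.92 ± 0.25), Cdh17 (-3.18 ± 0.70) and Cep131, the last at group means of at most 25.

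Of the lists in Δ(177-191) relative to vector 6 passed, and each also with an estimated correlation. Myc and ribosome biogenesis had 29 of 37 lower and 3 higher (adjusted over the list alone, 3 higher and 30 lower; adjusted p = 1.06e-15). The nucleolar genes Nolc1 (-1.46 ± 0.13) and Wdr12 (-1.25 ± 0.10) and Myc itself fell (-0.95 ± 0.13). G1/S and DNA replication had 20 of 39 lower (adjusted over the list alone, 1 higher and 23 lower; adjusted p = 1.02e-08). Lower were the thymidine kinase gene Tk1 (-1.19 ± 0.11) and Uhrf1 (-1.15 ± 0.15). Phagocyte oxidase and granulocyte receptors had 13 of 21 higher (adjusted over the list alone, 14 higher and 0 lower; adjusted p = 9.88e-09). Higher were the receptor genes C5ar1 (2.97 ± 0.70), Cxcr2 (2.23 ± 0.39) and Csf3r, the G-CSF receptor (1.93 ± 0.45). Monocyte and macrophage had 9 of 20 higher (adjusted over the list alone, 9 higher and 0 lower; adjusted p = 0.000108). Amino acid and stress response had 12 of 25 higher and 2 lower (adjusted over the list alone, 12 higher and 2 lower; adjusted p = 5.29e-06). Atf3 (3.0 ± 0.59) was up and Atf4 (-0.38 ± 0.10) down. Stem and progenitor transcription factors had 9 of 24 lower and 5 higher (adjusted over the list alone, 5 higher and 9 lower; adjusted p = 0.0167). Cbfa2t3 (-2.54 ± 0.13) and Myb were down and Meis1 (1.3 ± 0.43) up, and Nfe2 (0.70 ± 0.14) was higher relative to vector alone. Among the genes always named, Id1 (-0.67 ± 0.23) fell and Cebpg (0.66 ± 0.11), Id2 (1.08 ± 0.17), Abl1 (0.79 ± 0.15) and Bcr (0.85 ± 0.15) rose. Relative to vector, but not from the line's own 0 h, Cdk4 was lower (-0.34 ± 0.12) and Cebpb (0.87 ± 0.14) and Spi1 (0.41 ± 0.14) were higher. The Cdk4 call rests on 1 of 3 probe sets: the others were at -0.20 ± 0.12 and -0.37 ± 0.16 (adjusted p = 0.32 and 0.12). Of the other probe sets, 1 of 2 passed for each of Bcr, Cebpg and Id2 and 0 of 1 for Abl1. Cdk4, Id1 and Spi1 lost their call with no filter, and Meis1 with quantile normalization. The granule lists did not pass: secondary and tertiary granule had 5 of 15 higher and 4 lower, with Lcn2 (2.99 ± 0.20) up and the lysozyme gene Lyz2 (-2.0 ± 0.18) down.

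In Δ(177-191) relative to vector 4647 probe sets passed at 12 h, 2198 higher and 2449 lower, 856 and 507 of them by 2-fold or more. At 6 h 3778 passed and at 9 h 4707. Of the genes called at 12 h, 674 of 1272 higher and 808 of 1583 lower passed at all 3 times, and 953 and 1155 passed in the same direction from the line's own 0 h. Compared with vector at the same time, without its own 0 h, 9758 probe sets passed at 12 h. Without replicate 2 of every group 2877 passed at 12 h.

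**Figure D2:**
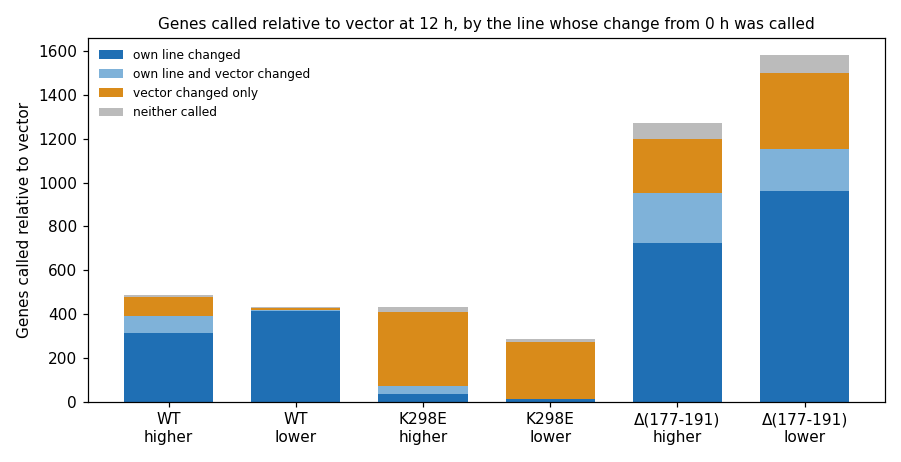
Number of genes called at 12 h relative to vector (bars from 0) for WT, K298E and Δ(177-191) cells, higher and lower, divided by whether the change from the line's own 0 h, the opposite change of the vector cells, both or neither passed the threshold. In K298E cells the vector change alone passed for 340 of 431 higher and 258 of 286 lower genes, in WT cells for 87 of 488 and 11 of 431.

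The mean change over 6, 9 and 12 h was compared directly between WT and each mutant. Such a difference does not show which line departed from vector cells. Against K298E, WT cells had the higher change of Igsf6 (4.02 ± 0.41), Mpo (2.96 ± 0.46), Tfec, a transcription factor gene of macrophages (2.76 ± 0.14), Il4 (2.71 ± 0.30) and Cd33, a sialic acid receptor gene of myeloid cells (2.5 ± 0.36). Tfec went from 196 ± 9.45 to 1389 ± 65.6 in WT cells and from 344 ± 14 to 304 ± 32.7 in K298E cells (SD, n = 3). The 5 lowest differences were Col9a3 (-2.89 ± 0.54), Pgf (-2.58 ± 0.42), Gm19696, Rgl3 and Akain1, the last 3 with group means of at most 21.7 in both lines. Col9a3 and Pgf fell in vector cells as in WT cells, with 9 of 9 treated arrays of each below every 0 h array. Myc and ribosome biogenesis had 25 of 37 members with the higher change in WT (adjusted over the list alone, 28 higher and 1 lower; adjusted p = 1.54e-15). The biosynthesis genes Cad (0.79 ± 0.07) and Srm (0.79 ± 0.08) were among them. Relative to vector at 12 h, this list and that of G1/S and DNA replication were lower in K298E cells. In WT cells G1/S did not pass, and the Myc call was lost with an estimated correlation. G1/S and DNA replication had 15 higher and 1 lower of 39 (adjusted over the list alone, 17 higher and 1 lower; adjusted p = 4.51e-06). Apoptosis and survival had 8 of 18 lower (adjusted over the list alone, 0 higher and 8 lower; adjusted p = 0.000667). These included the death genes Bbc3 (-0.93 ± 0.12) and Bcl2l11 (-0.92 ± 0.14) as well as the survival gene Bcl2 (-0.92 ± 0.14). Bbc3 and Bcl2l11 lay below every 0 h array on 9 of 9 treated arrays in WT and in vector cells. Bcl2 did so on 9 in WT and 6 in vector cells. Interferon response had 6 of 23 lower (adjusted over the list alone, 0 higher and 10 lower; adjusted p = 0.00204). Monocyte and macrophage had 7 of 20 lower (adjusted over the list alone, 0 higher and 7 lower; adjusted p = 0.00214) and stem and progenitor transcription factors 8 lower and 2 higher of 24 (adjusted over the list alone, 2 higher and 8 lower; adjusted p = 0.00395). BCR/ABL and STAT5 targets had 10 lower and 1 higher of 26 (adjusted over the list alone, 1 higher and 11 lower; adjusted p = 0.00214) and amino acid and stress response 10 lower and 1 higher of 25 (adjusted over the list alone, 2 higher and 11 lower; adjusted p = 0.00214). ID and basic helix-loop-helix had 4 of 11 lower (adjusted over the list alone, 0 higher and 4 lower; adjusted p = 0.0247). Phagocyte oxidase and granulocyte receptors were higher in WT, 6 against 1 lower of 21 (adjusted over the list alone, 6 higher and 1 lower; adjusted p = 0.0178). Estrogen receptor targets (0 higher and 3 lower of 13, adjusted over the list alone likewise; adjusted p = 0.0462) had an adjusted p = 0.169 with an estimated correlation.

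Against Δ(177-191), WT cells had the higher change of Igsf6 (4.2 ± 0.41), Prtn3 (2.77 ± 0.15) and the crossover gene Ccnb1ip1 (2.65 ± 0.20). Ankrd37, a hypoxia response gene (2.96 ± 0.30), fell in Δ(177-191) cells and did not pass as a change in WT cells at 12 h. The GTPase gene Gem (2.83 ± 0.33) fell in both lines, and further in Δ(177-191) cells. Emilin1 (-2.68 ± 0.15), C1qtnf1 (-3.2 ± 0.34), the cytokine gene Il1a (-2.95 ± 0.61), Smpdl3b (-2.74 ± 0.56) and Fosb (-2.65 ± 0.53) had the lower change in WT. C1qtnf1 was at 1.33 at 0 h in Δ(177-191) cells and could fall no further there. Myc and ribosome biogenesis had 26 of 37 higher (adjusted over the list alone, 29 higher and 0 lower; adjusted p = 5.05e-23), with Myc at 1.78 ± 0.11. G1/S and DNA replication had 20 of 39 higher (adjusted over the list alone, 23 higher and 0 lower; adjusted p = 2.44e-06). Hypoxia and glycolysis had 10 of 24 higher (adjusted over the list alone, 12 higher and 1 lower; adjusted p = 8.23e-05), with the hexokinase gene Hk2 at 1.99 ± 0.10. Amino acid and stress response had 20 of 25 lower (adjusted over the list alone, 0 higher and 23 lower; adjusted p = 2.23e-19), with Trib3 at -1.97 ± 0.17. Monocyte and macrophage (2 higher and 7 lower of 20; adjusted p = 0.019), BCR/ABL and STAT5 targets (2 and 8 of 26; adjusted p = 0.0215) and interferon response (1 and 8 of 23; adjusted p = 0.0251) were lower. Adjusted over the list alone, these had 2 higher and 7 lower, 2 higher and 9 lower and 1 higher and 10 lower. The cytosolic ribosomal proteins had 3 of 29 higher but a median of -0.33 and did not pass.

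The mean change differed between WT and K298E at 3714 probe sets, 1790 higher and 1924 lower in WT (2522 and 1302 with median centring), and between WT and Δ(177-191) at 5390, 2859 higher and 2531 lower. Relative to vector, the mean change passed for 1973 probe sets in WT, 1241 in K298E (769 higher and 472 lower, or 501 and 655 with median centring) and 5441 in Δ(177-191). Without replicate 2 of every group WT differed from K298E at 1765 probe sets and from Δ(177-191) at 3314. Relative to vector the counts were then 979 in WT, 343 in K298E and 3486 in Δ(177-191). Of the 488 genes higher in WT at 12 h, 114 were also higher in K298E, where independent lists of these sizes would share 16.4, and 321 in Δ(177-191), where 48.5 would be shared. Of the 431 lower genes, 13 were lower in K298E (9.63 for independent lists) and 41 higher, and 202 were lower in Δ(177-191) (53.3 for independent lists). The difference between WT and K298E at 12 h passed for 281 of the 488 and 365 of the 431 genes, in the direction of the WT change. That between WT and Δ(177-191) passed in this direction for 135 and 182 genes and in the other direction for 98 and 47.

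These overlaps share the vector arrays. Across 12800 genes, which are not independent replicates, the relative change in WT correlated with K298E at 0.323 and with Δ(177-191) at 0.430. Simulated groups without any change, set against a shared unchanged control, gave 0.498. The covariance exceeded its simulated value by 0.0585 for Δ(177-191) and lay at -0.00842 from it for K298E. In the simulation the vector change was noise alone, while vector cells changed at 3699 probe sets from 0 h to 12 h. That real change is subtracted from both lines, so these values cannot show what the constructs share. Between changes from each line's own 0 h, which share no arrays, the correlation was 0.178 with K298E and 0.347 with Δ(177-191), and 0.409 between WT and vector cells. Part of the overlap of calls may come from the shared vector arrays, which were not divided between the constructs.

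Vector cells, which carry no fusion, changed after 4-HT themselves. Trib3 fell from 590 ± 53.7 at 0 h to 198 at 12 h (SD, n = 3), a mean log2 change of -1.87 ± 0.12 (adjusted p = 8.83e-16), and the hormone gene Fgf21 by -2.18 ± 0.43. The other lowest changes were Col9a3 (-2.09 ± 0.38), Pgf (-2.08 ± 0.30), Flywch2 (-2.04 ± 0.31) and Haao, an enzyme of tryptophan breakdown (-2.01 ± 0.35). The 5 largest rises, Exosc6, Hpd, Insc, Rnf227 and Gm1123, had group means of at most 25.3, and Insc lost its call with no filter. Above that level the ribosome biogenesis genes Rrp12 (1.11 ± 0.13) and Utp20 (1.07 ± 0.08) and the replication genes Cdc6 (0.79 ± 0.10) and Ccne1 (0.76 ± 0.10) rose. Cebpa fell by -1.78 ± 0.12.

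By list, G1/S and DNA replication had 30 of 39 members higher and 0 lower in vector cells after 4-HT (adjusted over the list alone, 33 higher and 0 lower; adjusted p = 3.07e-20). Myc and ribosome biogenesis had 30 of 37 higher and 2 lower (adjusted over the list alone, 31 higher and 3 lower; adjusted p = 2.46e-20). Amino acid and stress response had 21 of 25 lower (adjusted over the list alone, 0 higher and 21 lower; adjusted p = 2.77e-20). Hypoxia and glycolysis had 17 of 24 lower (adjusted over the list alone, 0 higher and 17 lower; adjusted p = 1.45e-09) and immediate early 9 of 21 (adjusted over the list alone, 0 higher and 10 lower; adjusted p = 0.000236), with the AP-1 gene Junb at -0.99 ± 0.10. Sterol biosynthesis (1 higher and 10 lower of 20; adjusted p = 0.00079), C/EBP family and partners (1 and 6 of 17; adjusted p = 0.00195) and BCR/ABL and STAT5 targets (0 and 7 of 26; adjusted p = 0.00526) fell. So did interferon response (1 and 13 of 23; adjusted p = 0.00764), apoptosis and survival (0 and 6 of 18; adjusted p = 0.00764), phagocyte oxidase and granulocyte receptors (1 and 8 of 21; adjusted p = 0.00797) and monocyte and macrophage (0 and 6 of 20; adjusted p = 0.00916). Adjusted over the list alone, these 7 had 1 higher and 10 lower, 1 higher and 6 lower, 0 higher and 10 lower, 1 higher and 13 lower, 0 higher and 6 lower, 1 higher and 9 lower and 0 higher and 6 lower. All 12 calls also passed with an estimated correlation. The ratio of the 3' to the 5' Gapdh controls in vector cells was 0.835 to 0.880 at 0 h and 0.788 to 0.861 later. In all, 5063 probe sets passed, 2261 higher and 2802 lower (3510 and 1720 with median centring), 63 and 304 of them by 2-fold or more. Without replicate 2 of every group 2964 probe sets passed. The effect of 4-HT and that of time in culture cannot be separated in this comparison.

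**Figure D3:**
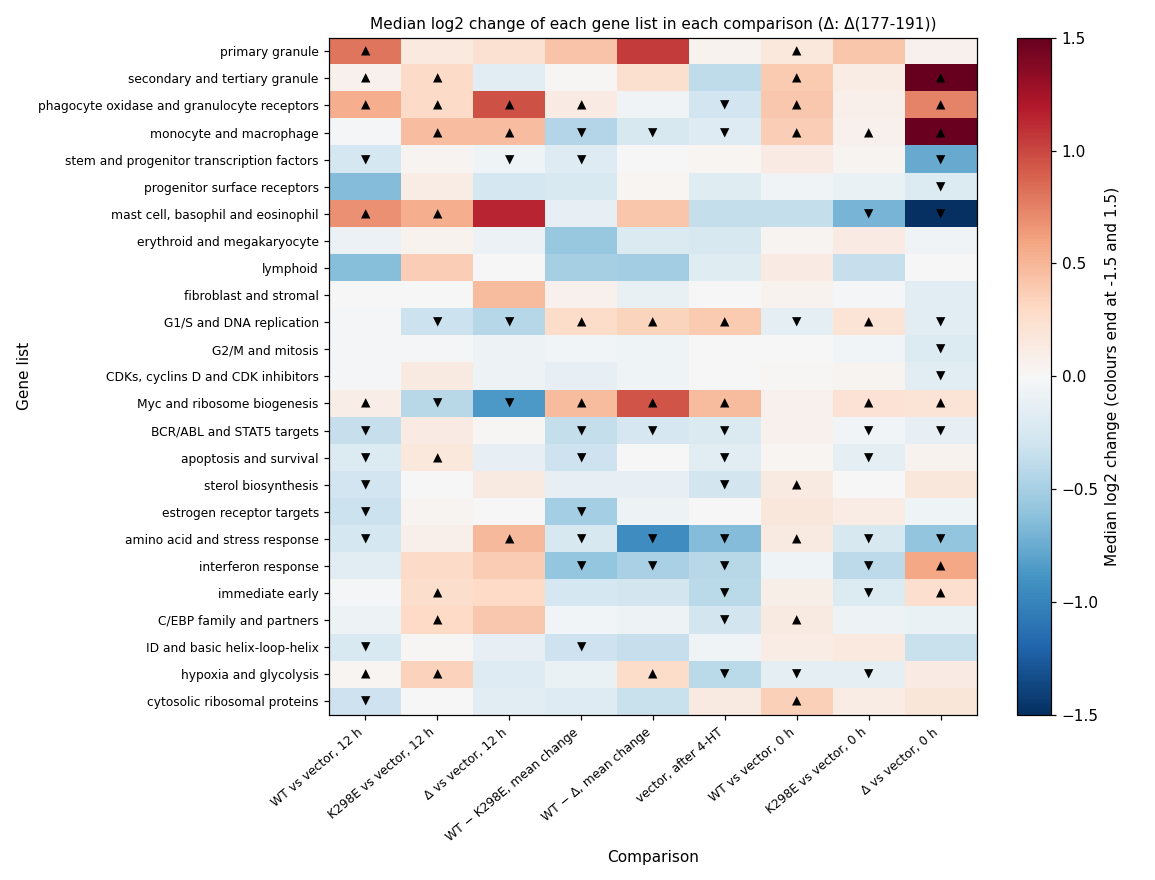
Median log2 change of the 25 gene lists (vertical axis, by name) in 9 comparisons (horizontal axis), as colour, with triangles where the list test passed, pointing up or down by its direction. In vector cells after 4-HT the medians of Myc and ribosome biogenesis and of amino acid and stress response were 0.47 and -0.65.

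The lines differed before 4-HT. At 0 h the Δ(177-191) line stood apart from vector at 6255 probe sets, 2834 higher and 3421 lower, 738 and 911 of them by 2-fold or more. Clec5a, a receptor gene of myeloid cells, was at 632 ± 26.4 against 1 ± 1 in vector cells (SD, n = 3; log2 difference 7.34 ± 0.39). S100a9, a calcium-binding protein of neutrophils, was at 598 ± 29.5 against 1 ± 1 (7.26 ± 0.31). Stfa2l1, a stefin gene (7.15 ± 0.33), and the platelet chemokine gene Ppbp (6.91 ± 0.25) were higher. Lower were Sox4, a transcription factor gene of progenitors, at 5 ± 1 against 1109 ± 91.1 (-7.12 ± 0.33). So were Maged1 (-6.23 ± 0.17), Trgv1 (-6.06 ± 0.23), Btg1 (-5.77 ± 0.25) and Stxbp6 (-5.54 ± 0.24). Myb (-1.34 ± 0.10) and Gata2 (-1.95 ± 0.08) were lower too.

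By list, secondary and tertiary granule had 12 of 15 higher at 0 h in Δ(177-191) cells (adjusted over the list alone, 12 higher and 0 lower; adjusted p = 3.22e-14). Monocyte and macrophage had 14 of 20 higher (adjusted over the list alone, 14 higher and 0 lower; adjusted p = 5.77e-11) and phagocyte oxidase and granulocyte receptors 11 of 21 against 1 lower (adjusted over the list alone, 13 higher and 1 lower; adjusted p = 1.14e-08). Stem and progenitor transcription factors had 17 of 24 lower and 1 higher (adjusted over the list alone, 2 higher and 17 lower; adjusted p = 5.77e-11) and mast cell, basophil and eosinophil 6 of 12 lower and 1 higher (adjusted over the list alone, 1 higher and 6 lower; adjusted p = 3.75e-06). In all 14 lists passed. The calls of G2/M and mitosis (adjusted p = 0.0306) and interferon response (adjusted p = 0.0353) were lost with an estimated correlation (adjusted p = 0.186 and 0.0504).

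In WT cells at 0 h 1104 probe sets differed from vector, 562 higher and 542 lower, and in K298E cells 1310, 603 higher and 707 lower (862 and 463 with median centring). Apart from Esr1, the WT line had higher signals of the chemokine genes Ccl6 (3.73 ± 0.24) and Ccl9 (3.71 ± 0.13), of Anxa3 (3.58 ± 0.19) and of the transporter gene Slco1a5 (2.97 ± 0.44). It had lower ones of Lta, a TNF family cytokine gene (-2.79 ± 0.49), Ankrd37 (-2.14 ± 0.26), C1qtnf1 (-1.84 ± 0.29), Sema7a (-1.79 ± 0.13) and Il6 (-1.77 ± 0.27). The K298E line had higher S100a9 (3.18 ± 0.31), Ppbp (2.85 ± 0.25), Ccl6 (2.6 ± 0.24) and Anxa3 (2.41 ± 0.19). It had lower Casp4 (-3.34 ± 0.18) and Casp1 (-3.08 ± 0.18), which are caspases of inflammation. Selenop (-2.76 ± 0.36), the urea transporter gene Slc14a1 (-2.53 ± 0.28) and the integrin gene Itgb3 (-2.53 ± 0.39) were lower too. Monocyte and macrophage had 7 of 20 higher and 1 lower in WT (adjusted over the list alone, 9 higher and 1 lower; adjusted p = 1.37e-11). In K298E Myc and ribosome biogenesis had 9 of 37 higher and 1 lower (adjusted over the list alone, 16 higher and 1 lower; adjusted p = 5.78e-12). In all 10 lists passed in each line. With an estimated correlation, cytosolic ribosomal proteins in WT (adjusted p = 0.477, and turned with quantile normalization) and monocyte and macrophage and BCR/ABL and STAT5 targets in K298E (adjusted p = 0.0519 with an estimated correlation, each) no longer passed.

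The 0 h differences overlapped. Of 372 genes higher in WT and 385 higher in K298E, 87 were shared, where independent lists would share 11.2, and of 359 and 441 lower genes 92, against 12.4. The shared vector arrays add to this overlap: across genes the correlation was 0.449, and 0.501 for simulated unchanged lines. Leaving out vector 0 h replicate 3 lowered the K298E count at 0 h to 829, leaving out K298E 0 h replicate 3 to 839, and leaving out WT 0 h replicate 2 lowered the WT count to 722. Without replicate 2 of every group the counts were 349 in WT and 356 in K298E.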

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

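The tests below, the splits of the arrays included, were chosen only after the result was seen, except that of a 0 h difference between the lines as the source of the K298E calls.

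The change after 4-HT differed between lines in tests of the difference itself. The mean change differed between WT and K298E at 3714 probe sets and in 11 gene lists, and between WT and Δ(177-191) at 5390 probe sets and in 7 gene lists. Of the genes always named, WT minus K298E was -1.75 for Cebpa, -0.88 for Gata2, -0.55 for Cdkn1a, -0.38 for Cebpg, 0.33 for Spi1, 0.59 for Myc, 0.96 for Gfi1 and 2.96 for Mpo (log2). WT minus Δ(177-191) was -1.28 for Csf3r, -0.84 for Abl1, -0.80 for Cebpg, -0.78 for Cebpa, -0.65 for Cebpb, -0.44 for Bcr and -0.39 for Id2. It was 0.42 for Cebpd, 0.51 for Gata2, 1.03 for Gfi1, 1.78 for Myc, 2.15 for Myb and 2.34 for Mpo.

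Most calls in K298E relative to vector at 12 h came with a change in the vector cells. Of the 717 genes called, a vector change alone passed for 83.4%. With each vector 0 h array left out in turn this share of the genes then called was 81.6% or more. The share cannot decide on the cause, since few of the called genes also changed in K298E cells. Of the 598 genes with a vector change alone, 456, 449 and 443 recurred without replicate 1, 2 and 3. This argues against a single such array as the cause for the genes that recurred. The genes called fell to 579, 570 and 552. With quantile normalization and median centring the share was 74.4% or more of the higher and of the lower genes, which by itself cannot decide either. Of the 598 genes, 551 recurred with quantile normalization and 459 with median centring. This argues against the scaling as the cause for the genes that recurred. With median centring 273 genes were higher and 458 lower, against 431 and 286. A difference between the lines at 0 h cannot be told apart from a lack of response: a median share of 0.435 of the relative change came from the 0 h difference. A response of vector cells to 4-HT, to time in culture or to the handling of the cultures at 0 h stays open, since no untreated later culture is in the series.

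Myb did not pass the threshold in WT cells and fell in Δ(177-191) cells. The choice of the Myb probe set was argued against, since the lower change of the 2 other probe sets in WT was 0.61. A single array was argued against, since with each of 12 arrays left out the change in Δ(177-191) nearest to 0 was -2.22. An exchange of the labels of both lines was not tested and stays open. A biological difference between the constructs stays open as well, since each has 1 line.

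The Δ(177-191) line differed from vector at 0 h at 6255 probe sets. Other cells mixed in part into its cultures were argued against as the cause of the strongest falls. Of 4578 genes at a signal of 200 or more in vector cells, 29 were over 8-fold lower, which remaining vector-like cells would have kept up. This does not cover the 2834 probe sets that were higher, since a small share of other cells could raise genes absent from vector cells. A culture replaced as a whole stays open too. Activity of the fusion before 4-HT as the whole cause cannot be told apart from other causes: among the 3646 genes called at 0 h, the difference correlated at 0.0848 with the change in WT minus that in K298E (0.0742 to 0.0930 with single arrays left out), and the deletion can change what the fusion does. The same holds for such activity at part of the genes: of the 488 genes higher in WT at 12 h, 193 were higher at 0 h in Δ(177-191) and 99 lower, and of the 431 lower genes 181 were lower and 104 higher. A difference between the lines unrelated to the construct cannot be told apart from one due to it, with 1 group per construct at 0 h.

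Whether other splits of the same arrays give counts as large was tested with 100 drawn splits per comparison, the real one included. For WT relative to vector 1 split was as large at 6 h (real count 1295, highest other 421). At 9 h there were 2 (1255 and 2112) and at 12 h 1 (1461 and 639). For K298E there were 3 at 6 h (256 and 1996), 2 at 9 h (1057 and 1421) and 2 at 12 h (1142 and 1265). For Δ(177-191) there were 3 at 6 h (3778 and 7687), 2 at 9 h (4707 and 4955) and 3 at 12 h (4647 and 6310). For mean changes there was 1 for WT minus K298E (3714 and 861) and 2 for WT minus Δ(177-191) (5390 and 5417). Against vector there was 1 for WT (1973 and 435), 2 for K298E (1241 and 1468) and 1 for Δ(177-191) (5441 and 3360). These splits between lines cannot decide whether chance explains a count. The lines differ at every time, 0 h included. A split that mixes lines within a group widens the spread there, and the median of the other splits was 0. A small share was thus set by the standing differences between the lines. For vector cells after 4-HT all arrays came from 1 line. There 1 split was as large, the real one (5063 and 2763), and the median of the others was 38. These other splits mix 0 h arrays with treated arrays within a group, which widens the spread there too. The real count was thus above that of every other drawn split. An effect shared by the 3 arrays of 0 h, such as their handling, would give the same, so the splits cannot exclude it. Some other splits called more than the real one, such as 1996 against 256 for K298E at 6 h. For a construct against vector at 1 time, every other split as large exchanged the lines more at 1 time than at the other. Such a split calls the differences between the lines. For the mean changes the exchanged arrays were not counted. At 0 h the 10 splits are too few for a share under 0.05, with 1 as large in each line: 1104 in WT (highest other 1), 1310 in K298E (0) and 6255 in Δ(177-191) (0).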

How the results depend on the processing

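The pseudocount of 32, the minimum signal of 50 and leaving out the 4 arrays with the highest top signal were chosen only after the results were seen. Of 466 results for named genes, calls were lost for 24 with no filter, 21 with median centring, 18 with the compared arrays alone, 11 with quantile normalization, 9 of 464 with a pseudocount of 1, 7 with a pseudocount of 12, 13 with 32, 3 without the 4 arrays, and 1 each with a replicate block and array weights. No call was lost of 415 with a filter on the mean or of 433 with a minimum signal of 50. These filters left the other named results, of low signal, untested, and fewer tests can ease the adjustment. The lack of losses therefore says little about results near the floor. Hp in WT minus Δ(177-191) reversed with a pseudocount of 32 (-0.14). The cause was not tested, here or below, except where named.

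The Gata2 change in K298E passed the threshold as a rise with quantile normalization (0.41; adjusted p = 0.0237), array weights (0.35; 0.0361), the compared arrays alone (0.35; 0.0276) and against vector at the same time (0.40; 0.000921). Its adjusted p ran from 0.000921 to 0.868 over all alternatives. Median centring reversed the Myb change in K298E (-0.051), which never passed, and gave 170 probe sets for K298E at 6 h. Array weights gave 2221 for WT and 1972 for K298E at 12 h, 417 for K298E at 6 h, 2001 for its mean change, and at 0 h 1853 for WT and 2307 for K298E. With a replicate block, WT at 12 h had 1517.

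Without subtracting the vector change, which asks another question, counts at 6, 9 and 12 h were 7099, 6754 and 6914 in WT, 2507 at 6 h and 488 at 12 h in K298E, and 6693 at 6 h and 7285 at 9 h in Δ(177-191). Against vector at the same time, which adds the 0 h differences, they were 3607, 3348 and 3424 in WT, 1542, 2093 and 1872 in K298E, and 8948, 10086 and 9758 in Δ(177-191). Of the gene lists, 9 instead of 14 passed in WT with an estimated correlation. With a replicate block 13 passed in WT, and 13 instead of 12 in vector cells after 4-HT. With fry, 18 instead of 6 passed in Δ(177-191), 18 instead of 11 in WT minus K298E, 17 instead of 7 in WT minus Δ(177-191) and 22 instead of 14 in Δ(177-191) at 0 h. With all probe sets of each member, counts fell to 11 of 14 in WT, 6 of 7 in WT minus Δ(177-191) and 9 of 10 in K298E at 0 h, and rose from 6 to 11 in Δ(177-191), from 10 to 11 in K298E, from 11 to 12 in WT minus K298E, from 12 to 14 in vector cells after 4-HT and from 14 to 17 in Δ(177-191) at 0 h. Scaling was tried on the 94 list calls only after they were seen. Quantile normalization lost 3 (estrogen receptor targets in WT, and at 0 h amino acid and stress response in WT and monocyte and macrophage in K298E), turned the direction of 2 (cytosolic ribosomal proteins in WT at 12 h and at 0 h, neither of which then passed) and gained 1 (secondary and tertiary granule in vector cells, lower). Median centring lost 1 (G2/M and mitosis in Δ(177-191) at 0 h) and gained 3 (interferon response in K298E, higher, and in vector cells secondary and tertiary granule, lower, and cytosolic ribosomal proteins, higher). It also turned the median of BCR/ABL and STAT5 targets in K298E at 0 h.

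With arrays left out, each count was lowest without replicate 2 of every group, and 7 counts were above the one with all arrays in some setting. Leaving out a replicate number takes 1 of 3 arrays from every group, so a fall need not come from that replicate. For WT at 12 h 2 of 15 settings lowered the count by more than 1.5-fold. No single array did, so leaving out another replicate number did so as well. The ranges at 6, 9 and 12 h were 573 to 1199, 592 to 1317 and 689 to 1371 for WT, 63 to 262, 311 to 934 and 313 to 1035 for K298E, and 2155 to 3595, 2762 to 4711 and 2877 to 4363 for Δ(177-191). For mean changes they were 1765 to 3790 for WT minus K298E, 3314 to 5524 for WT minus Δ(177-191), and against vector 979 to 2019 for WT, 343 to 1220 for K298E and 3486 to 5592 for Δ(177-191). Vector cells after 4-HT had 2964 to 4940, and at 0 h WT had 349 to 984, K298E 356 to 961 and Δ(177-191) 4341 to 5459. Gata2 ran from -0.78 to -0.60 in WT (weaker without replicate 2), from 0.29 to 0.41 in K298E and from -1.13 to -0.91 in Δ(177-191). Myb ran from 0.04 to 0.20, -0.011 to 0.094 (reversed in 2 settings) and -2.49 to -2.12. Of 8634 results for named genes with arrays left out, 731 lost their call and 0 reversed. Signals near the floor and 3 arrays per group limit the small changes that can be called.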

Other observations

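The hypotheses below and their tests were chosen only after the result was seen.

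A hypothesis is that the WT changes need DNA binding of the fusion. Over the 919 genes called in WT relative to vector at 12 h, the median change from a line's own 0 h, taken in the WT direction, was 0.10 in K298E, 0.129 of that in WT. This fits the hypothesis on that measure, but choosing the genes by their WT change raises the WT median. The median does not describe every gene. Of the largest WT rises, Gpr84, Anxa3 and Ccr1 lay above every 0 h array on 9 of 9 treated K298E arrays. Igsf6 and Tnfrsf14 did so on 8, Lcn2 on 6, Hp on 4, Vsir on 3, Il4 on 2 and Mpo on 1. Gpr84 signals in K298E cells were 53 to 81 at 0 h, 350 to 383 at 6 h and 116 to 199 at 12 h. Some WT rises were thus also seen in K298E cells. Relative to vector, the higher genes had a median of 0.25 in K298E against 0.73 in WT, and the lower genes 0.06 against -0.70. Only 12 h was used, when the own change passed for 488 probe sets in K298E, against 2507 at 6 h. Vector cells changed at 3699 at 12 h without a fusion, so a small change in K298E need not come from lost DNA binding. The lower signal of K298E cells on the Esr1 probe set used (860 to 1439, against 2107 to 2475 in WT) may also lower their response, which these data leave open.

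A further hypothesis is that the WT changes need the region deleted in Δ(177-191). The ratio was 0.707 for this line, with a median of 0.55, which may reflect a partial need, the same choice of genes, or the state of this line at 0 h, and does not decide between them.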
